A study of Mus musculus with 9 samples.

How the data were processed

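Poly(A) RNA was sequenced from adipocytes made in culture from the stromal vascular fraction of mouse inguinal fat, a subcutaneous depot whose precursor cells can form beige adipocytes, the inducible fat cells that express the uncoupling protein UCP1. Per the labels, confluent cells were kept for 48 hours in medium with 10% fetal bovine serum, 0.5 mM isobutylmethylxanthine, 125 nM indomethacin, 1 µM dexamethasone, 850 nM insulin, 1 nM T3 and 1 µM rosiglitazone, and then in medium with serum, insulin, T3 and rosiglitazone at the same doses. All libraries were taken at day 7. There were 3 libraries from C57BL/6J (B6), 3 from 129X1/SvJ (129) and 3 from F1 offspring. The labels do not say whether the libraries of a group came from separate animals or cultures, nor which strain was the mother of the F1, so p-values measure only the spread between these libraries.

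The deposited values were RPKM, reads per kilobase of summed exon length per 1000000 assigned reads, with 1 value per gene and library. The authors named the aligner STAR and genome build mm9. The read counter, the annotation release, the versions and any filter are not given in the sources used here. In each library, RPKM times exon length summed to 1000000 over all 24015 rows, so the denominator was the reads assigned to these genes. The values kept steps of 1 read, and from that step the number of assigned reads was recovered. With a tolerance of 0.1 read, 99.98% or more of the non-zero rows of every library then held a whole number of reads. The recovered depths were 25655940, 19130023 and 26931442 reads in B6 replicates 1 to 3, 23796152, 28473088 and 23710910 in 129, and 39686992, 53410960 and 50237320 in F1. Between replicate libraries, the spread of these reads was 3.83 to 15.1 times that of read counting alone, as chi-square over its degrees of freedom on genes with at least 20 reads per pair. Replicates therefore varied beyond counting error, and no pair of files was a copy.

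Of the 24013 gene symbols, 2 stood on more than 1 row and were represented by the row with the highest mean. A spreadsheet had turned 27 symbols into dates, 17 of them among the genes tested. These rows were kept under the text as deposited and none is named. Reads of 54 rows came from copies on more than 1 chromosome, 5 of them tested. Cells in 5 unnamed columns, on 31 rows, were not used. List members under an older or newer symbol were matched through synonyms (Gk is Gyk in these values). Coordinates are those of mm9.

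Genes with RPKM of at least 1 in at least 3 of the 9 libraries were tested, 11542 in all. Values were analysed as log2(RPKM + 1), which understates fold changes of genes near or below an RPKM of 1. limma 3.58.1 under R 4.3.3 was fitted with 1 mean per group and with a mean-variance trend, and all 9 libraries shared the estimate of spread. The contrasts were 129 minus B6, F1 minus B6, F1 minus 129, and F1 minus the mid-parent value, the mean of the parental log2 values. A moderated F-test covered the 3 groups. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Errors of log2 fold changes are standard errors from limma, and errors of RPKM are standard deviations over 3 libraries. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1. Gene lists were fixed before the data were examined. They were tested with camera from limma at a preset inter-gene correlation of 0.01 where at least 3 members were tested, which left 32 lists, and the adjustment ran over those lists. The same test with an estimated correlation, and fry, were run beside it. No list passed with an estimated correlation in any contrast. The smallest adjusted p there was 0.319 for 129 minus B6, 0.215 for F1 minus B6, 0.303 for F1 minus 129 and 0.222 for F1 minus the mid-parent value.

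Genes to be named were also fixed beforehand. From 129 minus B6 these were the 10 largest rises and 10 largest falls among genes past the threshold with an absolute log2 fold change of at least 1 and no overlap between the groups. The same rule gave 5 and 5 for F1 minus mid-parent, without the condition on overlap, and 3 and 3 for F1 against each parent. Predicted genes, microRNA hosts and RIKEN clones were left out. Ucp1, the 4 NFI genes, Nnt and the sex-linked genes were always named, with up to 4 members of each list that had the smallest p in 129 minus B6. Any other gene named is said to have been chosen after its values were seen.

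The procedure was tested on simulated data. Values of 11417 genes were given known changes in a simulated 129 minus B6 comparison. Of the genes changed 1.25-fold 68.8% were recovered, 100% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold. Of 200 calls, 20 were unchanged genes, which is 10% and above the nominal 0.05. The limit first set for this share was under 10%, and it was loosened after the value was seen. None of the unchanged simulated lists was called by camera among 21 tested, but other splits of the real 129 and B6 libraries called up to 11 lists, beside 6 in the real split.

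Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter at RPKM of 5, median-of-ratios rescaling, quantile normalization, no mean-variance trend, sample weights (arrayWeights), the replicate number as a block, other handling of repeated symbols, each library left out in turn, fits on only the 2 groups compared, and an added fold-change threshold. Chosen after seeing the data were voom on the recovered reads, reads thinned to the lowest depth, and a mid-parent value taken as the mean of the parental RPKM. Read-count models were not used for the main results, since the deposited values were already scaled, and voom on the recovered reads served only as an alternative. Allele-specific expression in F1 was not analysed here.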

Results

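RNA levels were measured in beige adipocytes differentiated for 7 days from inguinal stromal vascular cells of B6 mice, described by the series as prone to obesity, of 129 mice, described as resistant, and of their F1 offspring. Each group had 3 libraries. Depth was 19130023 to 26931442 assigned reads in B6, 23710910 to 28473088 in 129 and 39686992 to 53410960 in F1. All F1 libraries were thus deeper than all parental ones. Scd1, a desaturase of fatty acid synthesis, was the most abundant gene in every library and took 3.53% to 6.35% of the reads. Correlations of log2 values across genes, which are not independent replicates, were 0.994 to 0.998 within groups and 0.975 to 0.991 between them. The first principal component held 59.5% of the variance and ran from B6 (-22.4 to -19.2) through F1 (1.98 to 2.49) to 129 (18.6 to 18.8). The second held 19.5% and set F1 (-14.2 to -11.0) apart from both parents.

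**Figure D1:**
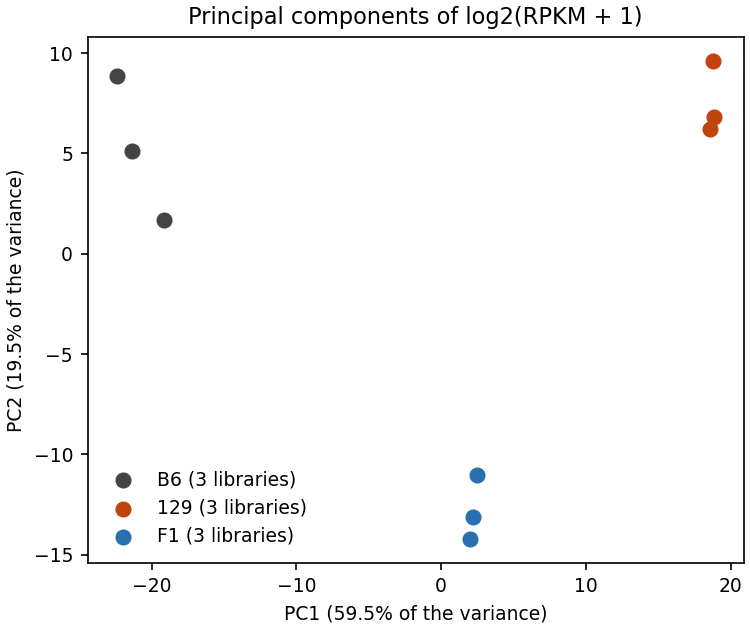
Principal components of log2(RPKM + 1) in the 9 libraries, with component 1 (59.5% of the variance) on the x axis and component 2 (19.5%) on the y axis, 1 point per library coloured by group. B6 and 129 sit at opposite ends of component 1, and the 3 F1 libraries sit between them and below both on component 2.

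The series asks how genetic variation between these strains bears on adipocyte browning, so 129 was first compared with B6. Ucp1, the mitochondrial uncoupling protein of thermogenic fat (chromosome 8, 85814247 to 85822355), had an RPKM of 9.88 ± 0.752 in B6 and 62.6 ± 1.96 in 129 (SD, n = 3 each), 6.34-fold higher in 129. Its log2 fold change was 2.55 (SE 0.05, adjusted p = 2.38e-10), and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Cidea, a lipid droplet protein of brown fat, rose from 6.93 ± 0.547 to 12.7 ± 1.38 RPKM (log2 fold change 0.79, SE 0.08). Other genes of the thermogenic programme went the other way. Cox8b, a cytochrome c oxidase subunit of brown fat, fell from 39.6 ± 1.34 to 21.1 ± 1.19 RPKM (log2 fold change -0.88, SE 0.06), and Adrb3, the beta-3 adrenergic receptor, fell from 54.0 ± 1.03 to 36.5 ± 0.714 RPKM (-0.55, SE 0.04). Chosen after their values were seen, the thermogenic coactivator Ppargc1a (-0.59, adjusted p = 8.53e-05) and the brown fat regulator Prdm16 (0.670 of the B6 level, adjusted p = 0.00576) were lower as well. Of the 18 brown fat thermogenic genes tested, 2 were higher, 11 lower and 5 did not pass, with the same counts adjusted over the list alone. The list as a whole had a median log2 fold change of -0.36 and a mean of -0.08 and did not pass (camera, adjusted p = 0.17, and 0.751 with an estimated correlation).

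Nfia, the transcription factor named in the series title (chromosome 4, 97248634 to 97785567), had an RPKM of 7.15 ± 0.462 in B6 and 7.98 ± 0.481 in 129. The log2 fold change of 0.14 (SE 0.06) did not pass (adjusted p = 0.105, exact two-sided permutation p = 0.2). It passed with sample weights (0.17) and without B6 replicate 2 (0.19). Its relatives Nfib (0.12, adjusted p = 0.0798), Nfic (0.02, adjusted p = 0.826) and Nfix (-0.16, adjusted p = 0.0624) did not pass either, so none of the 4 NFI genes differed over all genes or adjusted over the list alone (camera, adjusted p = 0.656). Nfib passed with median-of-ratios rescaling (0.15), with sample weights (0.13) and without F1 replicate 3 (0.12). Nfix passed in 4 settings, without B6 replicate 1 (-0.20), without F1 replicate 1, with the replicate block (-0.16 in both) and with voom (-0.17).

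**Figure D2:**
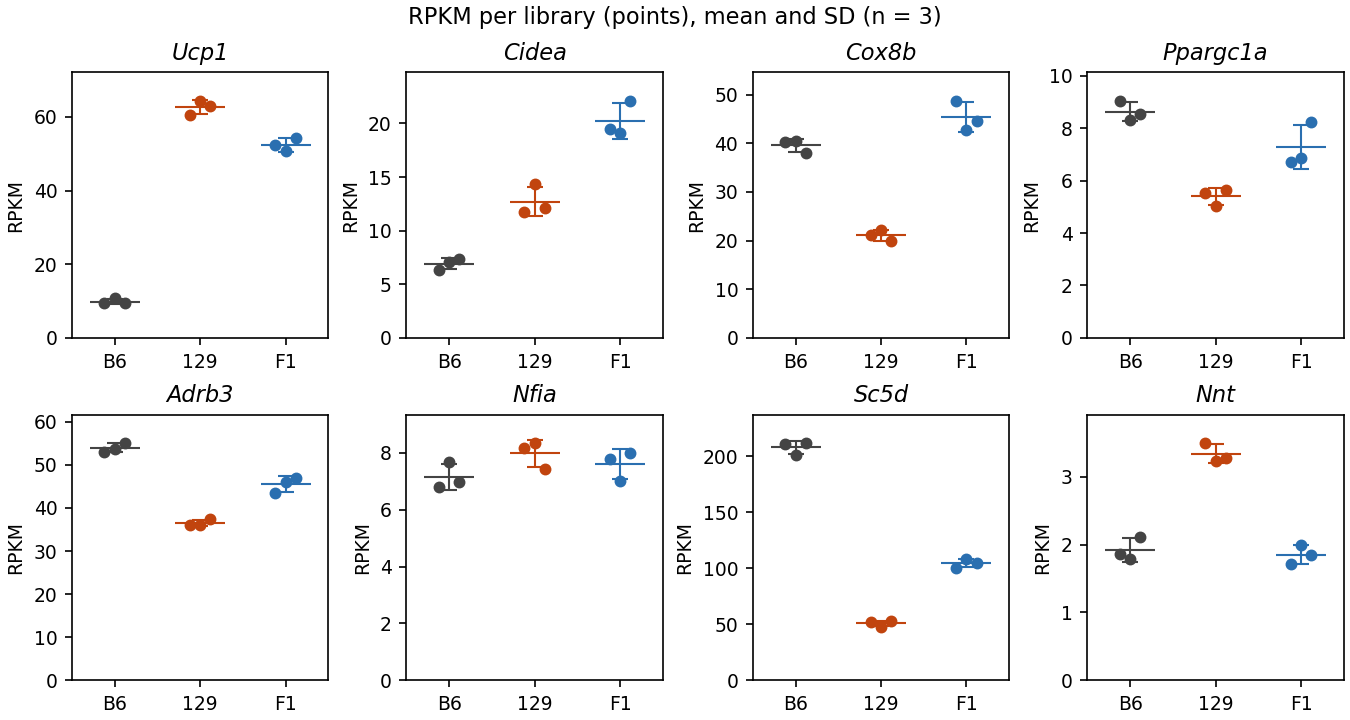
RPKM of Ucp1, Cidea, Cox8b, Ppargc1a, Adrb3, Nfia, Sc5d and Nnt on the y axis of each panel, by group on the x axis, with 1 point per library and bars for the mean and SD of 3 libraries. Ucp1 and Cidea are higher in 129 than in B6, Cox8b, Ppargc1a, Adrb3 and Sc5d are lower, and Nfia overlaps between the groups; Ppargc1a was chosen after its values were seen.

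Among all genes, the largest rise in 129 was that of Tpsab1, a mast cell tryptase (chromosome 17, 25480190 to 25482507), listed at 0 in 2 B6 libraries and at 56.0 ± 4.69 RPKM in 129 (adjusted p = 2.22e-11). Eno1b, an enolase sequence, rose from 5.12 ± 0.736 to 193 ± 5.65 RPKM, but its exons lie in copies on chromosomes 18 and 4, so its source is uncertain. The enolase gene Eno1 of the glycolysis list was listed at only 0.692 ± 0.147 RPKM in B6 and 0.689 ± 0.0226 in 129, too low to be tested. Ifi202b, an interferon-inducible DNA sensor of a gene family on chromosome 1, went from 0.00723 ± 0.0125 to 23.1 ± 1.57 RPKM, where reads shared with its relatives leave the size uncertain. Apoe, the apolipoprotein of lipid transport (chromosome 7, 20281593 to 20284515), rose 9.45-fold from 119 ± 10.5 RPKM (log2 fold change 3.23, SE 0.07), and Ucp2, a relative of Ucp1 in the mitochondrial carrier family (chromosome 7, 107641854 to 107650682), rose 9.13-fold from 20.2 ± 2.10 RPKM (3.13, SE 0.06). Also among the 10 largest rises were the lipid-antigen presenting paralog Cd1d2 (3.79, and 6.05 with a pseudocount of 0.1), Gchfr, the feedback regulator of GTP cyclohydrolase (3.61, and 5.79 with voom), AA465934 (3.17), Abhd1 (3.04) and the lipid receptor of macrophages Trem2 (3.02).

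On the log2(RPKM + 1) scale the largest fall was that of Sorl1, a sorting receptor of adipocytes and neurons (chromosome 9, 41776572 to 41932372), from 31.8 ± 0.660 to 0.282 ± 0.0195 RPKM (log2 fold change -4.67, SE 0.06, adjusted p = 2.22e-11). Cela1, a pancreatic-type elastase, fell by 3.11 on the log2 scale and Pttg1, the securin of mitosis, by 2.59. Trim30d and Trim12a, neighbouring members of the TRIM family on chromosome 7, were listed at 5.43 ± 2.61 and 5.27 ± 2.06 RPKM in B6 and at 0 and 0.0154 ± 0.0266 in 129, and as paralogs their reads are uncertain. Their log2 fold changes were -2.61 and -2.58, and -9.93 and -7.84 with voom. The small RNA genes Rnu73b and Snord53 were listed at 0 in all 129 libraries, beside 4.97 ± 1.13 and 4.92 ± 1.74 RPKM in B6. With voom their log2 fold changes were -4.24 and -4.08, much smaller than that of Trim30d at a like RPKM. They therefore rest on few reads, and their rank is uncertain. The remaining 3 of the 10 were Col28a1, a collagen (-2.45), Pdpn, podoplanin (-2.33), and Adh1, an alcohol dehydrogenase that oxidises retinol (-2.12).

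Of 5 lists of mitochondrial and lipid energy metabolism, oxidative phosphorylation and the citric acid cycle passed as lower in 129. For nuclear-encoded oxidative phosphorylation 0 of 51 genes were higher and 24 lower, or 0 and 30 adjusted over the list alone, with Sdha at 0.763 and Cox7a2 at 0.691 of the B6 level (camera, adjusted p = 1.49e-04; adjusted p = 0.751 with an estimated correlation). Of the 16 genes of the citric acid cycle and pyruvate dehydrogenase 12 were lower and 0 higher, or 12 and 1 adjusted over the list alone, among them Sucla2 (log2 fold change -0.64) and Cs, citrate synthase (-0.31). That list had an adjusted p of 0.0149, and 0.751 with an estimated correlation, and it missed the threshold without B6 replicate 3 (0.0527). Fatty acid oxidation had 13 of 23 genes lower and 3 higher, 13 and 4 adjusted over the list alone, including the isomerase Eci1 (-0.92) and the dehydrogenases Acadm (-0.70) and Acadl (-0.49), with an adjusted p of 0.143 that passed without B6 replicate 2 (0.0308). Lipolysis and adrenergic signalling had 5 of 10 lower and 1 higher (6 and 1 adjusted over the list alone), such as the protein kinase A subunit Prkaca (-0.38), and mitochondrial biogenesis regulators had 5 of 8 lower and 0 higher (6 and 0 adjusted over the list alone), such as Esrra (-0.33). Neither list passed (adjusted p = 0.0868 and 0.143).

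Cholesterol synthesis was the list with the smallest p. Of its 19 genes 17 were lower in 129 and 0 higher, or 18 and 0 adjusted over the list alone (camera, adjusted p = 3.35e-08; adjusted p = 0.319 with an estimated correlation). Sc5d, a desaturase of late sterol synthesis, fell from 208 ± 5.69 to 50.7 ± 2.61 RPKM (log2 fold change -2.02, SE 0.05). On chromosome 9 it lies within 500 kb of Sorl1, the largest fall, so the 2 falls may not be independent. Fdft1, squalene synthase (-0.55), and Mvd, a mevalonate pathway decarboxylase (-0.73), were lower too. Hmgcs1 was listed at 0 in all 9 libraries. Loss of 129 reads that differ from the reference would lower values in 129, and it was not measured for this or any other list.

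Extracellular matrix genes were higher in 129, with 13 of 22 higher and 1 lower, also adjusted over the list alone (camera, adjusted p = 9.69e-05; adjusted p = 0.751 with an estimated correlation). The proteoglycans Lum and Dcn rose 3.11-fold and 2.01-fold, and the fibrillar collagens Col1a2 and Col3a1 1.74-fold and 1.48-fold. Lum and Dcn are neighbours on chromosome 10 (96942134 to 97035337), so their rises may not be independent. Genes of endoplasmic reticulum and integrated stress had 7 of 17 higher and 1 lower, or 8 and 1 adjusted over the list alone (adjusted p = 0.00654; adjusted p = 0.751 with an estimated correlation). Among them were Fgf21, a stress-induced hormone (log2 fold change 0.92), Trib3 (0.67), and the transcription factors Ddit3 (0.57) and Xbp1 (0.51). Glycolysis and hypoxia genes had 6 of 20 higher and 1 lower, also adjusted over the list alone, such as the phosphofructokinase Pfkp (0.80) and the glucose transporter Slc2a1 (0.34). That list had an adjusted p of 0.0127, and 0.751 with an estimated correlation, and it missed the threshold without B6 replicate 1 (0.0692), without B6 replicate 3 (0.0519) and with fry (0.0978).

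Among markers of other cell types single genes passed, but none of the lists below passed with camera at the preset correlation. Smooth muscle and myofibroblast markers had 7 of 13 lower in 129 and 2 higher, also adjusted over the list alone (adjusted p = 0.195), with Myh11 and Actg2 at 0.415 and 0.355 of B6 and Cyr61 1.40-fold higher. Macrophage markers had 6 of 13 lower and 0 higher (8 and 0 adjusted over the list alone), such as C1qa at 0.513 of B6 (adjusted p = 0.0868), and the list passed with median-of-ratios rescaling (0.048), with the replicate block (0.0068) and without 129 replicate 2 (0.00813). Adipocyte progenitor markers had 5 of 12 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.28, passing at the higher filter with 0.0157). The receptor Pdgfra rose 1.85-fold, Cd34 rose 1.40-fold and Wnt2 was at 0.473 of B6. Of 4 endothelial markers tested 1 was higher and 3 lower, also adjusted over the list alone (adjusted p = 0.545, passing with no filter at 0.0119), with Pecam1 at 0.442 of B6 and Eng 1.83-fold higher. Among mature adipocyte genes 5 of 25 were higher and 8 lower, also adjusted over the list alone (adjusted p = 0.649), with Pck1 2.37-fold higher and Retn, resistin, at 0.474 of B6. Lymphocyte and mesothelial markers had no tested member. The only epithelial marker tested, Krt19, was 1.94-fold higher, and the 2 skeletal muscle markers tested did not pass (1 higher adjusted over the list alone). Tubb3 was the 1 of 3 glial and neuronal markers lower (log2 fold change -1.70, list adjusted p = 0.656), and of 3 bone and cartilage markers Comp was lower (-1.28) and Runx2 higher (0.22, a call lost without B6 replicate 1 or 3 and without 129 replicate 1 or 2, at 0.19 to 0.22, and 0.38 with a pseudocount of 0.1), with a list adjusted p of 0.593.

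Interferon response genes were high in B6 replicate 1. Their mean log2 value was 4.23 there, 2.64 and 2.88 in B6 replicates 2 and 3, 2.53 to 2.57 in 129 and 2.12 to 2.93 in F1. Of 20 genes 1 was higher in 129 and 3 lower, or 0 and 1 adjusted over the list alone, among them Gbp3 (17.6 ± 12.7 RPKM in B6 and 4.71 ± 0.507 in 129, log2 fold change -1.50, and -0.97 without B6 replicate 1). The list had an adjusted p of 0.0868 and passed in 6 settings, with the smallest value with sample weights (0.00246). Of 11 genes of MHC class I presentation 1 was higher, H2-K1 (log2 fold change 0.24), a call lost with no filter (0.24), with sample weights (0.17), without B6 replicate 2 or 3 (0.17 and 0.24) and without 129 replicate 2 or 3 (0.25 and 0.21), and none passed adjusted over the list alone (adjusted p = 0.696). Inflammation and acute phase genes had 5 of 14 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.313), with the haemoglobin scavenger Hp at 0.474 of B6 and Icam1 at 0.444.

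No other list passed with camera at the preset correlation. Glucocorticoid-induced genes had 5 of 10 higher and 1 lower, 6 and 1 adjusted over the list alone, such as Sgk1 (0.62) and the metallothionein Mt1 (0.77), with an adjusted p of 0.0681 that passed in 8 settings (0.0107 to 0.0492). Imprinted genes had 4 of 12 higher and 6 lower (4 and 7 adjusted over the list alone, adjusted p = 0.611), with Peg10 3.30-fold higher and Mest at 0.287 of B6. The counts of higher and lower genes were 1 and 3 of 13 for fatty acid synthesis (adjusted p = 0.633), 1 and 7 of 19 for adipogenic transcription factors (1 and 8 adjusted over the list alone, adjusted p = 0.312), 2 and 2 of 10 for brown lineage, beige and depot markers (3 and 3, adjusted p = 0.682), and 2 and 1 of 5 for UCP1-independent thermogenesis (adjusted p = 0.751). They were 1 and 5 of 21 for the cell cycle (1 and 4 adjusted over the list alone, adjusted p = 0.809), 3 and 4 of 12 for NRF2 antioxidant genes (4 and 4, adjusted p = 0.751), 3 and 2 of 9 for immediate early genes (adjusted p = 0.472) and 2 and 3 of 13 for circadian clock genes (adjusted p = 0.742). Where no second pair is given, the counts adjusted over the list alone were the same. Median and mean had opposite signs for UCP1-independent thermogenesis (-0.07 and 0.06) and for the cell cycle (0.01 and -0.07), and the depot and glial lists had medians within 0.01 of 0 against means of 0.05 and -0.53. With fry 18 of the 32 lists passed. Of those that camera did not call, these included mitochondrial biogenesis (adjusted p = 0.00184), lipolysis (0.0017), fatty acid synthesis (0.00742), fatty acid oxidation (0.0184), adipogenic transcription factors (0.0206), smooth muscle (0.00699), progenitor (0.031) and endothelial markers (0.0237), inflammation (0.00547) and imprinted genes (0.00493), and the glial and bone lists (0.00181 each).

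In total 4333 of the 11542 genes passed in 129 against B6, 1834 higher and 2499 lower, which became 2184 higher and 2075 lower after median-of-ratios rescaling. Of the 4333, 279 had an absolute log2 fold change of at least 1, 148 higher and 131 lower. In 5754 genes, or 49.9%, all 3 libraries of one strain lay above all 3 of the other, where chance gives 10%. The moderated F-test over the 3 groups called 5448 genes. The median SE was 0.06, so small log2 differences passed. On simulated data 10% of the calls were unchanged genes. That simulation changed few genes and gave all genes the same spread beyond counting, so its share need not hold for the real calls. The list calls at the preset correlation are weaker evidence: of the 10 splits of these 6 libraries, 6 called at least the 6 lists of the real split, and the highest other called 11.

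**Figure D3:**
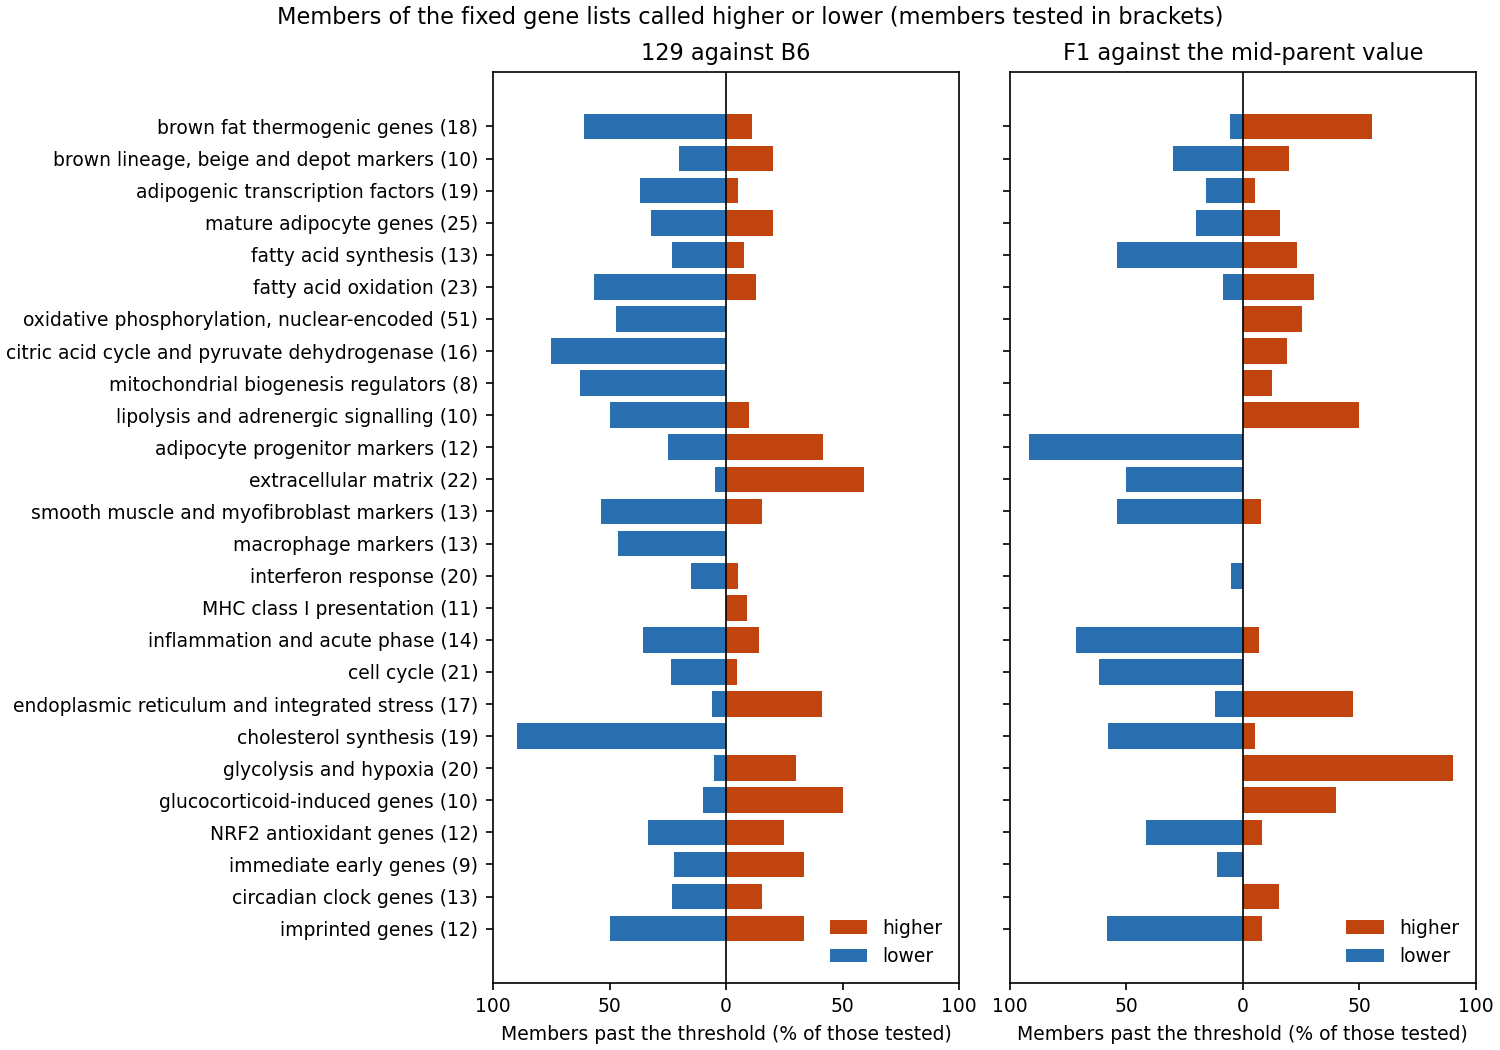
Percent of the tested members of each fixed list (y axis, lists with at least 8 tested genes) that passed the threshold as higher, drawn to the right of 0, or lower, drawn to the left, on the x axis, for 129 minus B6 and for F1 minus the mid-parent value. Cholesterol synthesis has 17 of 19 genes lower in 129, and glycolysis and hypoxia has 18 of 20 genes above the mid-parent value in F1.

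F1 libraries were then set against the mid-parent value, which additive inheritance on the log2 scale would give. Ucp1 in F1 was 52.4 ± 1.79 RPKM, 1.02 (SE 0.05) above the log2 mid-parent value (adjusted p = 1.75e-06). Against the mean of the parental RPKM the excess was smaller, 1.44 times that mean or a log2 ratio of 0.52 (adjusted p = 1.02e-04). Cidea reached 20.2 ± 1.65 RPKM, above both parents and 1.03 (SE 0.07) above the mid-parent value, and Cox8b reached 45.3 ± 3.05 RPKM, 0.63 (SE 0.05) above it. Adrb3 at 45.5 ± 1.84 RPKM was 0.03 above it, which did not pass. Of the 18 brown fat thermogenic genes 10 were higher than the mid-parent value, 1 lower and 7 did not pass, or 10 and 2 adjusted over the list alone (camera, adjusted p = 3.83e-06; adjusted p = 0.222 with an estimated correlation). Nfia at 7.60 ± 0.516 RPKM differed from it by 0.01 (adjusted p = 0.934). Nfix (-0.24, adjusted p = 0.0101) and Nfic (-0.16, adjusted p = 0.0269) were lower, calls that were lost for Nfix without F1 replicate 1 (-0.19) and for Nfic with median-of-ratios rescaling, with quantile normalization and without F1 replicate 1 (-0.14 each) and without F1 replicate 2 (-0.16), and 0 of the 4 NFI genes were higher.

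Glycolysis and hypoxia genes stood out in F1, with 18 of 20 higher and 0 lower, also adjusted over the list alone (camera, adjusted p = 3.22e-14; adjusted p = 0.222 with an estimated correlation). Pfkp rose to 46.8 ± 2.46 RPKM, 0.77 above the mid-parent value, and the lactate transporter Slc16a3 to 34.7 ± 2.08 RPKM, 0.54 above it. Oxidative phosphorylation had 13 of 51 genes higher and 0 lower (14 and 0 adjusted over the list alone, adjusted p = 2.69e-08), with Sdha 0.19 above. The citric acid cycle had 3 of 16 higher and 0 lower (adjusted p = 6.96e-04) and fatty acid oxidation 7 of 23 higher and 2 lower (adjusted p = 8.18e-04), each with the same counts adjusted over the list alone. With an estimated correlation the adjusted p of these 3 lists was 0.45, 0.45 and 0.453, and with fry they also missed the threshold (0.111, 0.0904 and 0.0807). Lipolysis and adrenergic signalling had 5 of 10 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00528; adjusted p = 0.222 with an estimated correlation).

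Progenitor and matrix lists were below the mid-parent value in F1. Of 12 adipocyte progenitor markers 11 were lower than the mid-parent value and 0 higher, also adjusted over the list alone (camera, adjusted p = 2.42e-06; adjusted p = 0.222 with an estimated correlation), with Cd34 at 0.568 and Pdgfra at 0.666 of the parental mean. Extracellular matrix had 11 of 22 lower and 0 higher, or 15 and 1 adjusted over the list alone (adjusted p = 7.17e-05; adjusted p = 0.291 with an estimated correlation), with Lum at 0.568 and Dcn at 0.649. Against B6 the matrix list did not pass, with 3 of 22 higher and 6 lower, or 4 and 7 adjusted over the list alone (adjusted p = 0.803). Smooth muscle and myofibroblast markers had 7 of 13 lower and 1 higher, 8 and 1 adjusted over the list alone, with Myh11 at 0.534. Their adjusted p of 0.0281, and 0.45 with an estimated correlation, missed the threshold in 4 further settings: without B6 replicate 2 (0.0654), without F1 replicate 1 (0.077), at the higher filter (0.0795) and with sample weights (0.0948). Inflammation and acute phase genes had 10 of 14 lower and 1 higher, or 12 and 1 adjusted over the list alone (adjusted p = 5.10e-04; adjusted p = 0.222 with an estimated correlation), with the adhesion molecule Icam1 at 0.477 of the parental mean. The cell cycle had 13 of 21 lower and 0 higher, or 18 and 0 adjusted over the list alone, with Rrm2, a subunit of ribonucleotide reductase, at 0.798 (adjusted p = 1.99e-05, 0.222 with an estimated correlation and 0.198 at the higher filter).

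Cholesterol synthesis was below the mid-parent value as well, with 11 of 19 lower and 1 higher, or 13 and 1 adjusted over the list alone (adjusted p = 2.33e-04; adjusted p = 0.222 with an estimated correlation), such as Mvd (-0.30). Sc5d at 105 ± 3.91 RPKM lay 0.02 above the log2 mid-parent value, which did not pass, and 0.30 below the mean of the parental RPKM on the log2 scale (log2 ratio -0.30, adjusted p = 9.98e-04). Endoplasmic reticulum and integrated stress genes had 8 of 17 higher and 2 lower, or 9 and 2 adjusted over the list alone (adjusted p = 3.19e-05; adjusted p = 0.222 with an estimated correlation), with Ddit3 and Trib3 both 0.48 above. Glucocorticoid-induced genes had 4 of 10 higher and 0 lower, or 7 and 1 adjusted over the list alone (adjusted p = 2.75e-04; adjusted p = 0.222 with an estimated correlation), with the metallothioneins Mt1 and Mt2 at 1.67 and 1.74 times the parental mean. Circadian clock genes had 2 of 13 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00998, 0.222 with an estimated correlation, 0.0508 without F1 replicate 3 and 0.0548 at the higher filter). In all, 15 of the 32 lists passed. Interferon response (adjusted p = 0.0866), macrophage markers (0.0768), and fatty acid synthesis, endothelial markers and imprinted genes (0.0728 each) did not pass, but each passed with camera in more than 1 other setting, with smallest values of 0.00208, 0.00436, 0.00472, 0.0485 and 0.0323. With fry, which tests a list against no change and not against other genes, the last 3 passed as well (4.58e-04, 4.58e-04 and 0.00112).

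Across genes 2676 were away from the mid-parent value, 964 higher and 1712 lower. After median-of-ratios rescaling these were 1298 higher and 1348 lower, so the excess of lower genes depended on the scaling. An absolute log2 difference of at least 1 was reached by 14, 11 higher and 3 lower. Tpsab1 (F1 level 26.0 ± 3.43 RPKM), Eno1b (1.70), Ifi202b (F1 level 10.8 ± 1.34 RPKM), Cela1 (1.23) and Cdsn, a skin adhesion protein (1.17, and 1.83 with a pseudocount of 0.1), had the largest rises, and Cyp2f2, a cytochrome P450 (-1.13), and Elovl4, a fatty acid elongase (-1.06), were the only falls that the rule on symbols admitted. Against the mean of the parental RPKM, which additive inheritance on the linear scale would give, Tpsab1 (-0.10) and Ifi202b (-0.094) turned direction without passing and Eno1b (0.15) no longer passed, while Cela1 (0.51), Cdsn (1.09), Cyp2f2 and Elovl4 (-1.21 each) passed. By that measure 2738 genes passed, 868 higher and 1870 lower.

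Set against each parent, F1 differed from B6 in 3599 genes, 1270 higher and 2329 lower, which became 1735 and 1753 after median-of-ratios rescaling. Changes of at least 1 on the log2 scale numbered 102, 55 higher and 47 lower. Tpsab1, Eno1b (4.19, of uncertain source as above) and Ifi202b rose most, and Elovl4 (-1.73), Sorl1 (-1.66) and Cyp2f2 (-1.61) fell most. Ucp1 was 2.30 higher than in B6 (SE 0.05, adjusted p = 1.41e-09). Of the lists 11 passed. They included glycolysis and hypoxia with 19 of 20 higher and 0 lower (adjusted p = 1.55e-12, 0.311 with an estimated correlation), cholesterol synthesis with 18 of 19 lower and 0 higher (adjusted p = 4.26e-10, 0.215 with an estimated correlation) and stress genes with 11 of 17 higher and 2 lower (adjusted p = 6.02e-06, 0.284 with an estimated correlation), all with the same counts adjusted over the list alone. Glucocorticoid-induced genes (6 of 10 higher and 0 lower, adjusted p = 1.08e-04, 0.284 with an estimated correlation), inflammation (10 of 14 lower and 1 higher, adjusted p = 7.14e-04, 0.284) and progenitor markers (8 of 12 lower and 0 higher, adjusted p = 0.00215, 0.311) passed as well, with 8 and 0, 11 and 1, and 8 and 0 adjusted over the list alone. Smooth muscle, endothelial, interferon, cell cycle and circadian lists passed (adjusted p = 0.0198, 0.0318, 0.0316, 7.14e-04 and 0.0432), but not with an estimated correlation (0.507, 0.284, 0.914, 0.39 and 0.311). Each also missed the threshold in at least 1 further setting, and the interferon list did so without B6 replicate 1 (0.113), without F1 replicate 2 or 3 (0.0578 and 0.119) and with fry (0.215). Without 1 library the smooth muscle list missed it for B6 replicate 2 (0.0653), and the circadian list for B6 replicate 2 (0.0569) and F1 replicates 2 and 3 (0.0508 and 0.119). Thermogenic genes had 7 of 18 higher and 4 lower, or 8 and 4 adjusted over the list alone, with a median of -0.015 and a mean of 0.23. Their adjusted p of 0.065 passed at the higher filter (0.0206), without F1 replicate 1 or 2 (0.041 and 0.0289) and with fry (9.12e-04).

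F1 differed from 129 in 3200 genes, 1387 higher and 1813 lower, and by at least 1 on the log2 scale in 80, 34 higher and 46 lower. Sorl1 (3.02, and 4.63 with a pseudocount of 0.1), Cela1 (2.78) and Pttg1 (2.06) rose most. The Wnt antagonist Sfrp4 (-2.10), the growth factor binding protein Igfbp5 (-2.06) and Cyp7b1, a hydroxylase of oxysterols (-1.87), fell most. Ucp1 was 0.25 lower than in 129 on the log2 scale (log2 fold change -0.25, adjusted p = 0.00557). Again 11 lists passed. Thermogenic genes had 12 of 18 higher and 3 lower, or 13 and 3 adjusted over the list alone (adjusted p = 1.51e-05, 0.303 with an estimated correlation). Oxidative phosphorylation had 30 of 51 higher and 0 lower, or 35 and 0 adjusted over the list alone (adjusted p = 7.39e-11, 0.548 with an estimated correlation). Extracellular matrix had 13 of 22 lower and 0 higher, or 17 and 0 adjusted over the list alone (adjusted p = 3.92e-07, 0.436 with an estimated correlation). Glycolysis and hypoxia, with 13 of 20 higher and 0 lower (16 and 0 adjusted over the list alone, adjusted p = 8.80e-07), and progenitor markers, with 9 of 12 lower and 0 higher (also over the list alone, adjusted p = 2.30e-05), reached 0.548 and 0.303 with an estimated correlation. The citric acid cycle, fatty acid oxidation and lipolysis lists were higher too (adjusted p = 4.22e-05, 1.22e-04 and 1.36e-04, and 0.548, 0.548 and 0.303 with an estimated correlation). Mitochondrial biogenesis, macrophage and cell cycle lists passed (adjusted p = 0.0301, 0.0143 and 0.00335), but not with an estimated correlation (0.303, 0.574 and 0.548). The macrophage list also missed the threshold with fry (0.173), without 129 replicate 1 (0.104) and without F1 replicate 2 (0.0951), and the mitochondrial list at the higher filter (0.0702), without 129 replicate 1 or 3 (0.0746 and 0.0521) and without F1 replicate 3 (0.0524). At the higher filter the cell cycle list turned direction and did not pass (0.734).

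Of the 279 genes with a parental difference of at least 1 on the log2 scale, 266 (95.3%) had an F1 mean between the parental means. On a scale from 0 at B6 to 1 at 129, the median position of F1 in RPKM was 0.371 for the 148 genes higher in 129 and 0.660 for the 131 lower, nearer the lower parent in both, and 0.52 over all. In log2 value it was 0.50 over all. From the log2 mid-parent value 153 of them differed, and from the mean of the parental RPKM 145, 25 higher and 120 lower. Among all genes tested, F1 passed as higher than both parents in 325 and as lower than both in 571. With F1 simulated at an additive level, these counts averaged 3.45 and 2.55 and reached at most 8 and 5 in 20 runs. Had the calls against each parent fallen on genes independently, 152.6 and 365.8 would have passed against both. Both comparisons share the F1 libraries and the estimate of spread, so their calls are not independent and an excess over these values decides nothing. The simulation set F1 at the additive level only, so it cannot tell inheritance from separate sequencing or culture of F1. Only 2 genes, the clones 6030408B16Rik and 8430408G22Rik, chosen after their values were seen, lay beyond both parents by at least 1 on the log2 scale, with F1 levels of 3.70 and 12.7 RPKM.

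**Figure D4:**
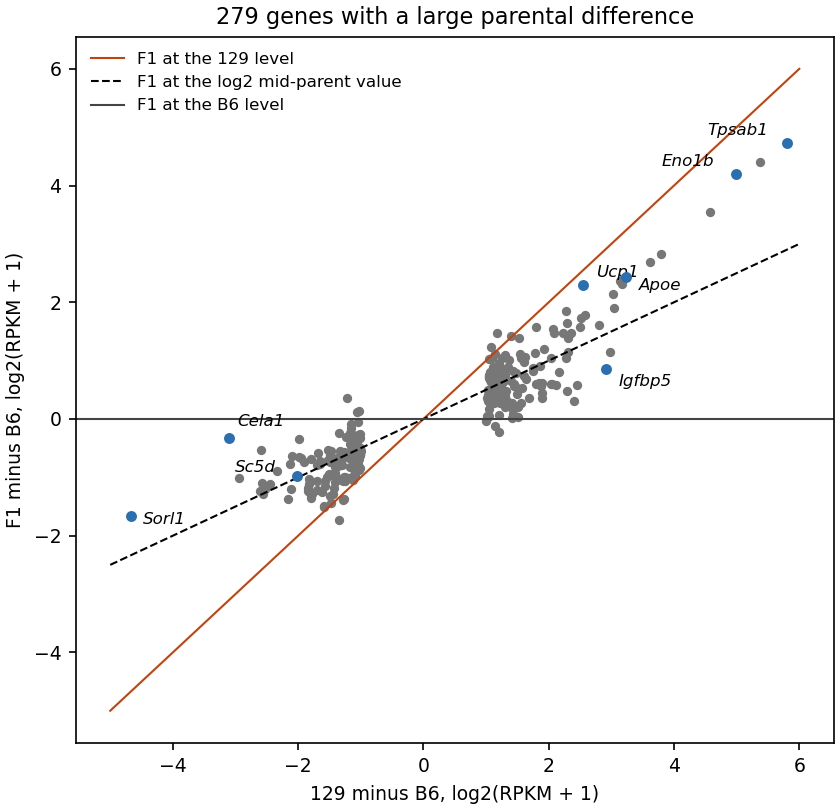
Log2 fold change of F1 over B6 (y axis) against that of 129 over B6 (x axis), 1 point for each of the 279 genes with a parental difference of at least 1 on the log2 scale. Lines mark F1 equal to B6, F1 equal to 129 and F1 at the mid-parent value, and 266 of the points lie between the parental lines.

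Labels were checked on genes of known strain or sex pattern. Nnt, which carries a deletion of several exons in C57BL/6J, was 1.92 ± 0.173 RPKM in B6 and 3.34 ± 0.141 in 129 (log2 fold change 0.57, adjusted p = 4.48e-05), and F1 was 1.85 ± 0.136. F1 thus lay at the B6 level (-0.03, adjusted p = 0.735) and below the mid-parent value (-0.32, adjusted p = 0.00249), not between the parents. The value covers all exons of the gene and does not measure the deleted exons alone, so Nnt cannot check the F1 label. Of the 279 genes with a large parental difference, 266 had an F1 mean between the parental means, as a hybrid would give. Xist, the RNA of the inactive X chromosome, stayed at or below 0.0294 RPKM in all libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in every group, with B6 means of 29.9 ± 3.18, 54.6 ± 3.91, 5.18 ± 0.225 and 7.62 ± 0.200 RPKM. Of these 4 genes, Kdm5d was lower in 129 (4.33 ± 0.230, adjusted p = 0.0239), a call lost without B6 replicate 1 or 2, without 129 replicate 1 or 3 (-0.21 to -0.19) and with thinned reads (-0.16), and the list did not pass (adjusted p = 0.633).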

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

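Of the settings below, voom on the recovered reads, thinned reads and the mean of the parental RPKM as mid-parent value were chosen after seeing the data; the others were fixed before the data were examined. The 8 main results, which are the counts of genes and lists, Ucp1 and Nfia, gave 189 values, and 181 of them kept their direction, their side of the threshold or, for counts, a size within 1.5 times. The exceptions were Nfia in 129 against B6, which passed with arrayWeights (0.17) and without B6 replicate 2 (0.19), and 6 counts. An added absolute log2 fold change of at least 1 left 279 genes in 129 against B6, 102 in F1 against B6, 80 in F1 against 129 and 14 away from the mid-parent value, since it is a stricter rule. Of the lists, 0 passed in 129 against B6 with an estimated correlation and 18 with fry, and the cause was not tested. With 1 library left out, the genes called ranged from 3532 (without B6 replicate 1) to 4487 in 129 against B6, from 2597 to 3733 in F1 against B6, from 2238 to 3528 in F1 against 129, from 1799 to 3048 for the mid-parent value and from 4508 to 5640 for the F-test. In these fits the lists past the threshold ranged from 5 to 9, Ucp1 from 2.52 to 2.61 and Nfia from 0.11 to 0.19. Among the other settings, the lowest counts of genes came with the filter at RPKM of 5, which tests fewer genes (3192, 2691, 2419, 2086 and 4049 in the same order), and the highest with arrayWeights (5528, 4891, 3608, 3542 and 6758). Named genes gave 6860 values over 301 results, of which 6590 kept their side, 199 no longer passed, 68 newly passed and 3 turned direction: Tpsab1 (-0.10), Ifi202b (-0.094) and Sc5d (-0.30), all with the mean of the parental RPKM, which lies above the log2 mid-parent value by construction. Gene lists gave 3152 values over 128 results, of which 2985 kept their side, 80 no longer passed, 85 newly passed and 2 turned direction in F1 against 129: endothelial markers with no filter (adjusted p = 0.0224) and the cell cycle at RPKM of 5 (adjusted p = 0.734), and the cause was not tested. The values that kept their side include 89 for genes and 63 for lists that turned direction while neither value passed. Pseudocounts of 0.1 and 0.5 changed no call among the 437 results compared, but they changed log2 sizes of genes low in a group, and Tpsab1 in 129 against B6 went to 8.89 at 0.1. The replicate block gave 4267, 3546, 3066, 2587 and 5299 genes and 9 lists. Replicate numbers showed no clear pairing across groups (correlations of residuals from -0.19 to 0.22). Between B6 and 129 these were all positive (0.07 to 0.22), and 5 of 9 libraries correlated best with their own number. A pairing is therefore not excluded. Depth limited the counts: with all libraries thinned to the lowest depth, 3908, 3208, 2840, 2364 and 4944 genes and 6 lists passed, and with voom 4280, 3891, 3470, 3125 and 5553 genes and 7 lists.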

Other observations

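The tests of strain variants and of a lower share of adipocytes for the thermogenic genes, the test of the division into higher and lower genes, and the test of separate sequencing or culture were chosen only after the results were seen, and so were the thinned reads. Cell-type lists did not move together in 129. The mean log2 value of 22 extracellular matrix genes was 7.69 ± 0.0688 in B6 and 8.01 ± 0.0526 in 129, with all 129 libraries above all B6 libraries. Those of smooth muscle (3.84 ± 0.0347 and 3.55 ± 0.0621), macrophage (1.90 ± 0.10 and 1.45 ± 0.326) and endothelial markers (2.19 ± 0.0652 and 2.04 ± 0.0198, on only 4 of 13 markers) were lower in every 129 library, and mature adipocyte genes (8.51 ± 0.0613 and 8.46 ± 0.0320) overlapped. In F1, progenitor markers (3.88 ± 0.0526) and the 4 endothelial markers (1.88 ± 0.0224) were below every library of both parents.

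Of the 276 genes with a large difference between the strains 96 lay in 42 runs along the genome, and the others had no such neighbour within 500 kb. The longest, on chromosome 11 from 82705647 to 83392138, held Fndc8, Slfn8, Slfn2, AA465934 and Ccl9, with 3 higher and 2 lower in 129. Slfn genes act in immune cell quiescence, and Ccl9 is a chemokine. Over all 42 runs, 35 of 54 adjacent pairs (64.8%) had the same direction, beside 50.1% if directions were independent. That difference was not tested. Genes named in this paragraph beyond those of the report were chosen after their values were seen.

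Ucp1 and Cidea were higher in 129 while 11 of the other 16 thermogenic genes tested were lower and 5 did not pass. Loss of 129 reads that differ from the reference lowers values, so it is excluded for Ucp1 and Cidea, whose lower log2 fold change was 0.79. For the lower genes it cannot be told apart from a real fall: the list's median of -0.36 lay at the percentile of 0.01 among random matched lists, the smallest that 10000 draws can give, but the list was weighed because its genes were low, and it did not pass camera (adjusted p = 0.17, and 0.751 with an estimated correlation). The same limit holds for other genes lower in 129. Medians of cholesterol synthesis, oxidative phosphorylation, the citric acid cycle and fatty acid oxidation lay at percentiles of 0.01, 0.03, 0.09 and 0.81. Mature adipocyte genes lay at 12.6 and extracellular matrix at 100. These lists too were weighed after their values were seen, so the percentiles cannot decide. A lower share of adipocytes was predicted to raise the markers of all other cells together. The smooth muscle list changed by -0.29 beside 0.31 for extracellular matrix, so they did not rise together. That cannot decide, because the prediction was written after these values were seen and the make-up of the other cells can differ between cultures. Mature adipocyte genes overlapped between the strains (8.51 ± 0.0613 in B6 and 8.46 ± 0.0320 in 129). A difference between the strains in this programme may remain and was not tested further, and with 1 strain per group it cannot be separated from differences in how each culture was grown.

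Many genes of F1 were away from the mid-parent value. Deeper sequencing and scaling by abundant genes do not explain the count of 2676, since 2364 passed with reads thinned to the lowest depth and 2646 after median-of-ratios rescaling. Of these genes 64.0% were lower, and 50.9% after rescaling, but rescaling centres the values, so scaling and a real excess of lower genes cannot be told apart. Separate sequencing or culture of F1 cannot be told apart from inheritance, because the labels name no batch that F1 shared with a parent. Even the shallowest F1 library had 1.39 times the reads of the deepest parental one, but depth alone shows neither separate sequencing nor separate culture. Non-additive inheritance may contribute and stays untested. A different make-up of cells in the F1 cultures may also contribute and was not tested. Mean log2 values of progenitor (3.88) and the 4 endothelial markers (1.88) in F1 lay below every parental library. Those of matrix (7.61) and smooth muscle genes (3.50) lay below both parental means but not below every library. Macrophage markers (1.80) and mature adipocyte genes (8.49) lay between the parental means.

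Genes with a large difference between the strains lay near each other more often than random draws of genes. Of 276 such genes 96 had another within 500 kb, beside a mean of 63.5 and a highest value of 95 in random draws (permutation p = 1e-04, the smallest 10000 draws can give), which argues against chance placement. With gene families in a row left out, 64 of 235 such genes had another within 500 kb (permutation p = 0.02). Random draws there gave a mean of 46.6 and a highest value of 80. An excess thus remained, but related or overlapping genes under unlike names can stay in that set. The test therefore cannot tell whether reads shared between neighbouring genes are the whole cause. Variants that differ between the strains in blocks and act on several genes may explain the nearness of these genes. That was not tested, and neighbouring genes of similar function in the same cells stay possible as well.

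Other splits of the libraries were fitted in the same way. For 129 against B6 the real split gave 4333 genes and the highest other 1, for F1 against B6 3599 and 1, and for F1 against 129 3200 and 0, with 1 of 10 splits as large in each, and 10 splits are too few for a share under 0.05. Lists past the threshold in 129 against B6 numbered 6 in the real split and 11 in the highest other. There 6 of 10 splits were as large, so the number of lists called at the preset correlation does not set the real split apart. For the F-test 1 of 100 splits gave as many as the real 5448 (highest other 1612), so a chance division of these libraries can be excluded at that level. The labels do not say whether the libraries of a group were separate cultures, so a chance difference between cultures is not excluded. For the mid-parent value 1 of 100 splits drawn from 840 gave as many as the real 2676, but most of the others mix B6 and 129 and so widen the spread within groups. The highest other split, 2543 genes, had the 3 B6 libraries in the place of F1, splits with the 3 129 libraries there gave 1993 and 1892, and one with the 3 F1 libraries kept and the parents mixed gave 441, beside a median of 0. With a parent in the place of F1 the count is large wherever the parents differ, even if F1 is additive. These splits therefore reflect the structure of the groups and cannot decide whether the count of 2676 sets F1 apart from the parents.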
